A study of Homo sapiens with 6 samples.

How the data were processed

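The samples are cultures of MDA-MB-231, a human triple-negative breast cancer cell line, transfected with a small interfering RNA (siRNA) against YB1 or with a control siRNA labelled NC. YB1 is the Y-box binding protein encoded by YBX1. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with the Illumina TruSeq RNA kit from total RNA, and sequencing used an Illumina NovaSeq instrument. There were 3 libraries in each of the 2 groups. The sources do not say whether libraries of a group came from separate cultures. All p-values therefore measure only the spread between these samples, which may be technical. Groups and library numbers came from the sample titles. The source names count the last digit of the cell line's name upward from library 1 to 3 in the controls, and the digit of YB1 in the other group. The cell line and genotype fields and the treatment text give MDA-MB-231, NC and YB1 for all libraries of each group, and these were used.

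The authors deposited whole-number read counts per gene for each library, and these counts were the values tested. Per the file headers, the deposited tables also hold FPKM values (fragments per kilobase of transcript, scaled to library size), which were not tested. The authors' deposited comparison of the groups holds a mean signal of normalized counts per group, a log2 fold change and p-values per gene, per the file headers. Those mean signals equalled the counts divided by DESeq2 size factors to within 4.9e-08% in the control group (genes with a control mean of at least 10). The aligner, the counting tool and the use of strand are not given in the sources used here. The submitters' processing notes name the mouse build mm10, while the deposited gene identifiers are human. Of 61868 rows, 58352 identifiers matched GENCODE release 29 of the human assembly GRCh38, and 98.7% of those started within 10 kb of the annotated start on the same chromosome. Coordinates are those of the deposited tables, read as GRCh38 from this match. The tables hold 316 unnamed gene models, which took 0.0751% to 0.0898% of counts per library and were kept.

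Counts were fitted in edgeR 4.0.16 under R 4.3.3 with TMM factors, the default expression filter by group (16170 genes kept) and the quasi-likelihood F test. Tests were two-sided, with Benjamini-Hochberg adjustment and a 5% false discovery rate. Levels are CPM (counts scaled to a common library size of 1e+06) on TMM-scaled library sizes, given as mean ± SD. A log2 fold change is the YB1 siRNA group over the NC siRNA group, and its SE is the size of the change over the square root of F. Gene lists (39, fixed before the data were examined) were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the 36 lists with at least 5 tested members. YBX1 itself was left out of every list. Camera compares a list with the other genes. Camera with an estimated correlation and fry were alternatives.

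Genes were named by a rule fixed before the data were examined. It took YBX1 with its paralogs, the 12 largest rises and 12 largest falls past the test among protein-coding genes (mean CPM at least 5, groups not overlapping), the 4 genes with the smallest adjusted p in each list past the list test, the 2 smallest in any other list with a gene past the test, and 12 published YB-1 targets. The 1 gene that passed is counted but not reported here by name. Further genes among the 25 smallest p were named after their values were seen.

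Alternatives fixed before the data were examined were DESeq2 size factors, library size alone, no count filter, at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, and protein-coding genes only. Chosen after seeing the data were corrections for gene length and for length with GC content (natural splines with 5 degrees of freedom per library, entered as offsets), library quality weights in voom, a robust dispersion fit, and the correction together with leaving out NC siRNA 2. GC content came from the longest transcript of each gene in GENCODE release 29 and was found for 97.5% of tested genes.

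The pipeline was tested on simulated counts with the real means, dispersions and library sizes for this comparison (15919 genes, 200 changed). It recovered 35.8% of the genes changed by a fold of 1.5, 83.6% at 2 and 95.5% at 4, with 14 unchanged genes among 161 calls. In simulated lists of 30 genes, all 4 lists lowered by 0.3 log2 were called and 0 of 16 unmoved lists. The simulated genes were drawn independently, while estimated inter-gene correlations in the real lists reached 0.64. The simulated shift was also larger than the median shift of any list called lower (furthest -0.19, G2/M and mitosis). The list simulation therefore does not show how often correlated lists or smaller shifts are called. With a simulated GC trend in 1 control library (15901 genes), the correction raised the calls from 106 to 155 and brought the common dispersion from 0.0303 to 0.0166. Total counts were 15395313 to 22341110 per library. A gene with 0 counts in a library could be present at up to 0.134 to 0.195 CPM (3 counts), a limit that covers counting error only.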

Results

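RNA of MDA-MB-231 cells, a human triple-negative breast cancer line, was sequenced after transfection with NC siRNA or with siRNA against YB1, with 3 libraries per group. The comparison asks which transcripts differ in these cells when YB1 is targeted. YB1 is a cold shock domain protein that binds DNA and RNA. Total counts were 16706478, 17906719 and 15395313 in NC siRNA libraries 1 to 3 and 15855418, 20616737 and 22341110 in the libraries labelled YB1 siRNA 1 to 3.

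YBX1, the gene for YB1 (ENSG00000065978, chromosome 1, 42682418 to 42703805, GRCh38), was not measurably lower in the libraries labelled YB1 siRNA. Its level was 733, 562 and 779 CPM in NC siRNA libraries 1 to 3 and 652, 651 and 643 CPM in the libraries labelled YB1 siRNA. The means were 691 ± 114 and 649 ± 5.19 CPM (SD, n = 3 each). The log2 fold change was -0.09 ± 0.12 (SE), with an edgeR adjusted p of 0.866, and its 95% interval of 78.0% to 113% of control excludes a halving of the transcript. Without NC siRNA 2, the control with the lowest level, the log2 fold change was -0.22 (adjusted p = 0.0264). Over the alternatives tried, the log2 fold change stayed negative and the adjusted p ran from 0.0189 to 0.998. In the authors' deposited table, which rests on the same counts, the log2 fold change of YBX1 was -0.08, with an adjusted p of 0.944. Reads of YBX1 may be split with its processed pseudogenes, whose summed counts were 6.85% to 10.2% of those of YBX1. The target transcript thus gives no check of the labels, and every direction below is between libraries as labelled. The paralog YBX3 was at 141 ± 3.23 and 138 ± 5.36 CPM (adjusted p = 0.948). YBX2 had 0 counts in each control library and 0, 1 and 4 counts in the libraries labelled YB1 siRNA, and was not tested.

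**Figure D1:**
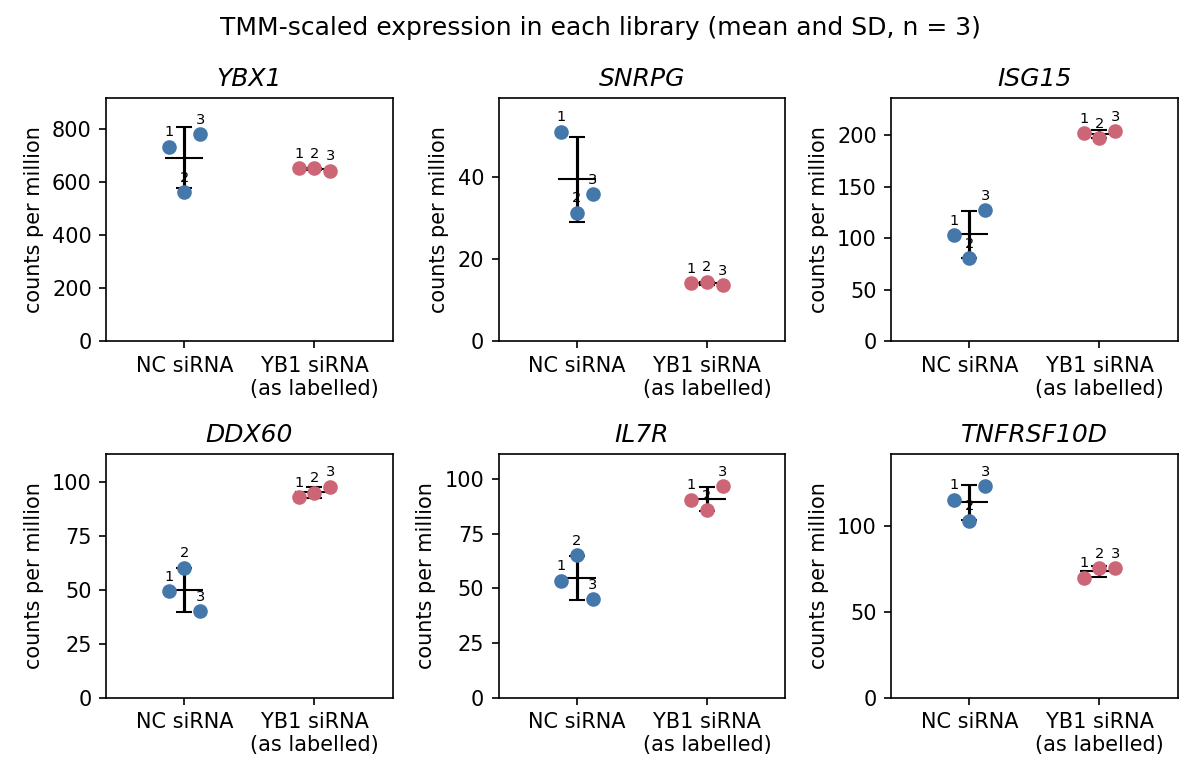
Level of 6 genes in each library, in CPM on TMM-scaled library sizes (linear axes from 0), with points numbered by library, horizontal marks for the mean and bars for the SD (n = 3). YBX1 lies between 562 and 779 CPM in both groups, while the groups do not overlap for SNRPG, ISG15, DDX60, IL7R and TNFRSF10D, none of which passed the edgeR test with all 6 libraries.

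Few single genes passed the edgeR test between the groups as labelled, with 1 of 16170 higher in the libraries labelled YB1 siRNA. The number higher was 0 in limma-voom, with a replicate block, and without NC siRNA 1, YB1 siRNA 1, YB1 siRNA 2 or YB1 siRNA 3. No gene was lower at the 5% threshold in edgeR, and none passed with a change of at least 2-fold in either direction. At an unadjusted p under 0.05 there were 728 higher and 706 lower genes, where chance alone gives 808.5 in total. DESeq2 called 32 genes higher and 28 lower, 4 of them at least doubled and 1 at least halved, and limma-voom called 0 (1457 genes at an unadjusted p under 0.05). The groups did not overlap for 2956 genes, or 18.3%, against 10% by chance.

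The number of genes called depended on 1 control library. Leaving out NC siRNA 2 gave 777 genes higher and 895 lower, 39 of them at least doubled and 23 at least halved. Leaving out any other library gave at most 2 higher and 1 lower. NC siRNA 2 stood apart on the first principal component (60.7% of variance; score 31.4 against -19.7 to 2.32 for the other libraries). Its deviation from the mean of the libraries fell with transcript GC content (Spearman rho across genes -0.68, against 0.09 to 0.34 for the other 5; genes are not independent replicates). Its mitochondrial share of counts was 12.1%, against 9.24% to 9.98%. The trend with gene length was strongest in NC siRNA 3 (Spearman rho across genes -0.33, against 0.26 in NC siRNA 2). The other libraries lay between -0.16 and 0.10. NC siRNA 2 and NC siRNA 3 also had the lowest voom quality weights (0.12 and 0.43). A correction for gene length and GC content, chosen after seeing the data, gave 15 genes higher and 12 lower with all 6 libraries.

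**Figure D2:**
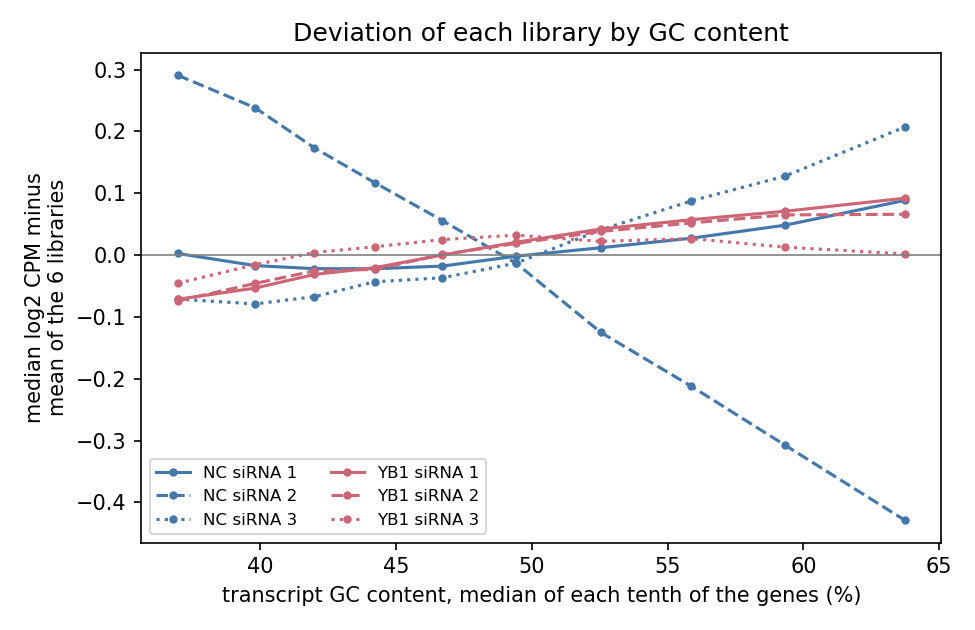
Median deviation of each library from the mean of the 6 libraries, in log2 CPM, against the median GC content (percent) of the tested genes in 10 bins of rising GC. Colours mark the groups and line styles the library number. NC siRNA 2 runs from 0.29 in the genes lowest in GC to -0.43 in those highest in GC, and the other 5 libraries stay between -0.08 and 0.21.

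Further genes with the smallest p were chosen after their values were seen, and none of them passed the edgeR test with all 6 libraries. SNRPG, a core Sm protein of spliceosomal small nuclear ribonucleoproteins (ENSG00000143977, chromosome 2, 70281362 to 70293740), was at 39.5 ± 10.3 CPM in controls and 14.1 ± 0.452 CPM in the libraries labelled YB1 siRNA. Its log2 fold change was -1.48 ± 0.18 (SE), with an adjusted p of 0.0698 (2.06e-08 without NC siRNA 2, 0.0271 without NC siRNA 3, and from 3.37e-19 to 0.938 over all alternatives). DDX60, an interferon-induced helicase, was at 49.9 ± 10.1 and 95.3 ± 2.52 CPM (log2 fold change 0.93, adjusted p = 0.157). The decoy death receptor TNFRSF10D was at 114 ± 10.0 and 73.3 ± 3.21 CPM (log2 fold change -0.63, adjusted p = 0.157). The gel-forming mucin MUC5AC was at 5.34 ± 1.64 and 13.3 ± 0.514 CPM (log2 fold change 1.31, adjusted p = 0.157). SPOCK1, a secreted proteoglycan, was at 11.4 ± 2.18 and 21.4 ± 1.62 CPM, and IL7R, the interleukin-7 receptor, at 54.6 ± 10.1 and 91.1 ± 5.52 CPM (adjusted p = 0.210 and 0.225). Without NC siRNA 2, DDX60, TNFRSF10D, MUC5AC, SPOCK1 and IL7R each passed the test in the same direction. That fit reused the libraries in which these genes were chosen and called 1672 of 16433 genes, so it is not an independent check. The authors' deposited table has an adjusted p below the 5% threshold for 42 genes, 22 higher and 20 lower. All 42 went in the same direction in edgeR, 1 of them past the test, and DESeq2 called all 42. The deposited comparison rests on the same counts, so this is not an independent check. For these 42 genes the deposited log2 fold change was at a median of 0.779 times the log2 ratio of the deposited group means.

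Of the 36 tested gene lists, camera placed 13 lower and 5 higher than the other genes in the libraries labelled YB1 siRNA. The shifts were small, and with an estimated inter-gene correlation none of the 18 calls held (lowest adjusted p = 0.26 with an estimated correlation). No list member passed the gene test adjusted over all genes, so member values below are given without a call. Adjusted over the list alone, 3 interferon-stimulated genes passed, with 1 member each of the G2/M, mitochondrially encoded, small-subunit ribosomal and drug efflux lists and 0 of the other 13 called lists. Median, mean and test had the same sign in all 18 lists. Over the alternatives, the lowest adjusted p of each of these lists ran from 6.82e-15 to 0.0244 and the highest from 0.26 to 0.812. After the length and GC correction, calls were lost for mitochondrially encoded transcripts (0.278), autophagy and lysosome (0.215), drug efflux (0.146), the nuclear-encoded respiratory chain (0.0923), published YB-1 targets (0.0724) and epithelial markers (0.0643). The length correction alone ended the mitochondrially encoded (0.0725) and autophagy calls (0.0511). Quality weights ended those of published YB-1 targets (0.291), DNA repair (0.104), mitochondrially encoded transcripts (0.0514) and translation factors (0.063). The stricter count filter ended those of translation factors (0.0519) and published YB-1 targets (0.0812), and replication-dependent histones were not tested under it. No count filter ended those of epithelial markers (0.185) and published YB-1 targets (0.0586). The call of published YB-1 targets was also lost with protein-coding genes only (0.0743) and with a replicate block (0.0748).

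Cell cycle genes gave the strongest list calls, and all of their calls held whichever library was left out. In the G2/M and mitosis list, 34 of 35 members had lower values, with a median log2 fold change of -0.19 (camera adjusted p = 3.56e-09; adjusted p = 0.26 with an estimated correlation). NUF2, a kinetochore protein, was at 56.4 ± 1.59 and 42.0 ± 1.69 CPM, and the mitotic kinase CDK1 at 130 ± 10.8 and 103 ± 7.78 CPM. In the G1/S and DNA replication list, 33 of 36 members had lower values (median -0.17, camera adjusted p = 1.24e-06; adjusted p = 0.444 with an estimated correlation). The cyclin CCNE2 was at 25.5 ± 1.01 and 19.3 ± 0.517 CPM, the ribonucleotide reductase subunit RRM2 at 136 ± 4.41 and 111 ± 7.50 CPM, and the replication clamp PCNA at 107 ± 7.31 and 88.7 ± 2.02 CPM. Without NC siRNA 2, 7 members of each of these lists passed the gene test, all of them lower. DNA damage repair genes also shifted lower (22 of 31 members with lower values, median -0.09, camera adjusted p = 0.00913; 0.542 with an estimated correlation), a call lost without NC siRNA 2 (median -0.03, adjusted p = 0.414), while the median was -0.15 without NC siRNA 3.

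Chaperone lists shifted lower as well. Cytosolic heat shock proteins had lower values in 18 of 20 members (median -0.12, camera adjusted p = 0.00216; 0.26 with an estimated correlation), with HSP90AA1, an inducible HSP90, at log2 fold change -0.26 ± 0.10 (SE). Endoplasmic reticulum chaperones had lower values in 19 of 22 members (median -0.09, camera adjusted p = 0.00635; 0.444 with an estimated correlation), with the HSP70-family chaperone HSPA5 at -0.22 ± 0.09 (SE). The median was -0.13 for the endoplasmic reticulum list without YB1 siRNA 3.

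Ribosomal, translation and respiratory chain lists were called lower, but these calls depended on single libraries. Small-subunit ribosomal proteins had lower values in 26 of 32 members (median -0.10, camera adjusted p = 0.00635; 0.589 with an estimated correlation), and RPS29 was at 156 ± 23.1 and 101 ± 6.42 CPM. Large-subunit ribosomal proteins had lower values in 29 of 44 members (median -0.08, camera adjusted p = 0.0289; 0.725 with an estimated correlation), and RPL23 was at 360 ± 11.9 and 280 ± 1.62 CPM. Without NC siRNA 3 the medians were -0.02 and 0.04 (adjusted p = 0.544 and 0.418), and without NC siRNA 2 they were -0.24 in both (8.17e-13 and 6.82e-15). The large-subunit call was also lost without NC siRNA 1 (0.162; median -0.04) or YB1 siRNA 3 (0.0503). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. Translation factors (22 of 35 lower, median -0.07, adjusted p = 0.0289; 0.444 with an estimated correlation) and the nuclear-encoded respiratory chain (28 of 36 lower, median -0.08, adjusted p = 0.0113; 0.589 with an estimated correlation) lost their calls without NC siRNA 3 (medians -0.0037 and -0.0094, adjusted p = 0.211 and 0.812). The respiratory chain call was also lost without NC siRNA 1 (0.0665), and its median was -0.20 without NC siRNA 2. Mitochondrially encoded transcripts had lower values in 12 of 13 members (median -0.14, adjusted p = 0.00216; 0.542 with an estimated correlation), a call lost without NC siRNA 2 (0.394; median -0.03), the library with the highest mitochondrial share. Without NC siRNA 3 the median was -0.24. MT-ND6, the member with the smallest p, was at log2 fold change -0.54 ± 0.09 (SE). It lies on the opposite strand to the other mitochondrial protein genes, and the use of strand in counting is not given.

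Spliceosome genes shifted lower (22 of 33 members, median -0.10, camera adjusted p = 0.011; 0.26 with an estimated correlation; 0.077 without NC siRNA 3). The Sm core proteins SNRPD3 and SNRPD1 were at log2 fold changes of -0.38 ± 0.10 and -0.31 ± 0.09 (SE). Cholesterol biosynthesis genes shifted lower (16 of 25, median -0.10, camera adjusted p = 0.0106; 0.444 with an estimated correlation), with the sterol oxidase MSMO1 at -0.41 ± 0.11 (SE), a call lost without NC siRNA 3 (median -0.04, adjusted p = 0.0995) or YB1 siRNA 3 (median -0.08, adjusted p = 0.117).

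Interferon-stimulated genes shifted higher in the libraries labelled YB1 siRNA, through part of the list. Of 33 members, 20 had higher values (median 0.07, camera adjusted p = 0.0106; 0.444 with an estimated correlation; 0.0954 without NC siRNA 3). The median was 0.16 without NC siRNA 2, 0.04 without NC siRNA 3 and 0.11 without YB1 siRNA 3. ISG15, a ubiquitin-like modifier, was at 104 ± 23.1 and 201 ± 3.65 CPM (log2 fold change 0.95, edgeR adjusted p = 0.157), and IFI44 at 78.0 ± 3.48 and 114 ± 2.06 CPM (0.54, adjusted p = 0.157). HERC6, a ligase induced by interferon, was at 31.5 ± 5.26 and 46.7 ± 0.894 CPM. Without NC siRNA 2, 9 members were higher and 0 lower past the gene test.

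Replication-dependent histones had higher values in 8 of 8 tested members (median 0.38, camera adjusted p = 0.00576; 0.26 with an estimated correlation; median 0.25 without YB1 siRNA 3), with H2AC6 at 11.3 ± 1.82 and 15.4 ± 1.31 CPM. Only 8 of the list's 17 genes with deposited counts were tested, and the groups did not overlap for 2 of these 8. The members H2BC21, H2BC4 and H4C14 were low, with group means of at most 2.70 CPM. With at least 50 counts in 3 libraries the histone list was not tested, so its call has no result under that filter. Drug efflux transporters had higher values in 9 of 12 members (median 0.19, adjusted p = 0.00914; 0.444 with an estimated correlation; 0.0974 without NC siRNA 3), with ABCC3 at 53.8 ± 1.92 and 68.9 ± 1.03 CPM. Autophagy and lysosome genes had higher values in 25 of 31 members (median 0.06, adjusted p = 0.0159; 0.542 with an estimated correlation), with the lysosomal hydrolase HEXA at 39.9 ± 2.48 and 50.9 ± 3.52 CPM, a call lost without NC siRNA 1 (0.137) or YB1 siRNA 3 (0.11). Epithelial markers had higher values in 12 of 15 members (median 0.17, adjusted p = 0.0382; 0.446 with an estimated correlation), a call lost without NC siRNA 1 (0.0742), NC siRNA 2 (0.283; median 0.06), YB1 siRNA 1 (0.0568) or YB1 siRNA 2 (0.069). The splicing factor ESRP2 was low at 0.909 ± 0.0515 and 1.73 ± 0.306 CPM.

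**Figure D3:**
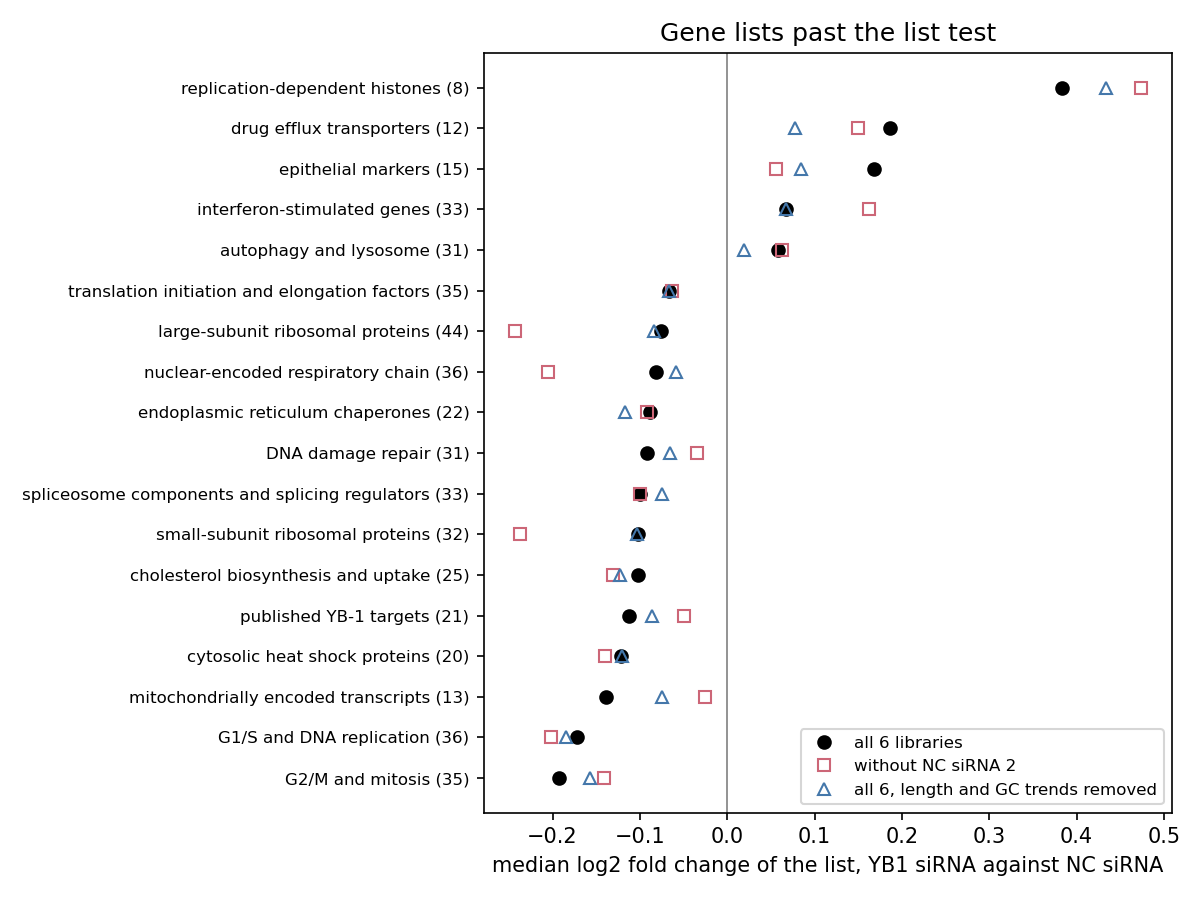
Median log2 fold change, YB1 siRNA over NC siRNA as labelled, of the 18 gene lists past the camera test, with the number of tested members in brackets. Filled circles show all 6 libraries, squares the medians without NC siRNA 2 and triangles those after removing gene length and GC trends. The medians with all 6 libraries run from -0.19 for G2/M and mitosis to 0.38 for replication-dependent histones.

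Published YB-1 targets had lower values in 14 of 21 tested members (median -0.11, camera adjusted p = 0.0484; 0.444 with an estimated correlation), and the call was lost when any library other than NC siRNA 3 was left out (adjusted p from 0.0512 to 0.637). The median was -0.05 without NC siRNA 2 and -0.19 without NC siRNA 3, and the call was kept in 6 of 20 alternatives. Of the list's members, PCNA, CDC6 and POLA1 are also in the G1/S list, and CCNA2, CCNB1 and TOP2A in the G2/M list. CHEK1 is also in the DNA repair list. The call is thus not separate from those of these lists, and the list without the shared members was not tested. None of the tested single targets named here passed the edgeR test with all 6 libraries. The cyclin CCND1 was at 573 ± 37.4 and 494 ± 11.4 CPM (log2 fold change -0.22, adjusted p = 0.533). EGFR was at 462 ± 94.0 and 510 ± 28.1 CPM and MET at 253 ± 46.9 and 259 ± 13.7 CPM (adjusted p = 0.797 and 0.965). EGFR passed without NC siRNA 2 (log2 fold change 0.30, adjusted p = 0.0176), with adjusted p from 0.0176 to 0.998 over the alternatives. CD44, ITGA6, HIF1A and G3BP1 had log2 fold changes of -0.07, -0.11, -0.12 and -0.12, and ERBB2 and MYC of 0.20 and 0.17 (adjusted p from 0.668 to 0.885 for these 6). SNAI1 had 4 to 9 counts per library, ABCB1 at most 1 and TWIST1 0, and none of them was tested.

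The other 18 tested lists did not pass (camera adjusted p from 0.0613 to 0.998). These were integrins and focal adhesion, glycolysis and hypoxia response, integrated stress response, MAPK feedback and immediate early genes, stress granule and mRNA-binding proteins, luminal breast markers, inflammatory cytokines and NF-kB targets, matrix metalloproteinases, nuclear-retained transcripts as a sign of RNA quality, NRF2 targets, apoptosis regulators, stemness markers, p53 targets, the TGF-beta pathway, fatty acid synthesis, YAP and TEAD targets, MHC class I antigen presentation, and mesenchymal factors. The integrin list passed without NC siRNA 2 (0.00237) or YB1 siRNA 1 (0.0321), and the glycolysis list without NC siRNA 3 (0.00697) or YB1 siRNA 1 (0.0185). Both lists also passed with all 6 libraries under other settings, with no count filter (0.0346 and 0.0117), at least 50 counts in 3 libraries (0.023 and 0.042), protein-coding genes only (0.0436 and 0.0473) and quality weights (0.0465 and 0.0459). Integrated stress response genes and stress granule proteins passed without NC siRNA 3 (0.0375 and 0.0244), and the stress granule list also after the length correction (0.0398). Median, mean and test differed in sign in 4 of these lists (stemness, fatty acid synthesis, MHC class I and mesenchymal factors). Adjusted over the list alone, 1 member each passed in the integrin, p53 and MHC class I lists and 0 in the other 15. Markers of other cells were low. Leukocyte markers summed to 1.85 to 3.25 CPM per library, and markers of fibroblasts and endothelium to 31.9 to 36.8 CPM. With the cold shock domain list, these lists had under 5 tested members and were not tested as lists.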

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

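Length and GC corrections, quality weights, the robust fit and the correction without NC siRNA 2 were chosen after seeing the data. DESeq2 size factors, library size alone, at least 50 counts in 3 libraries, protein-coding genes only and the robust fit kept all 7 main results on their side. For genes higher, lower, at least doubled and at least halved (1, 0, 0 and 0 in edgeR), the values were 41, 28, 9 and 3 with no count filter, 32, 28, 4 and 1 in DESeq2, 4, 3, 2 and 1 after the length correction, 15, 12, 1 and 1 after the length and GC correction, 1118, 1286, 139 and 62 with quality weights, and 677, 1013, 46 and 15 with the correction and without NC siRNA 2. Limma-voom gave 0 genes higher. With 1 library left out the ranges were 0 to 777 higher, 0 to 895 lower, 0 to 39 doubled and 0 to 23 halved. For these changes the cause was not tested, apart from the trends, depth and markers of NC siRNA 2.

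With 1 library left out, the YBX1 log2 fold change ran from -0.22 to -0.0095, the lists called higher from 3 to 6 and those called lower from 8 to 12. YBX1 passed its threshold with quality weights (-0.17) and with the correction and without NC siRNA 2 (-0.19). Lists called higher and lower (5 and 13) went to 0 and 0 with an estimated correlation, and to 1 and 0 in fry, which asks another question. After the length and GC correction, 2 lists were higher. The list test was not run for DESeq2. The median of large-subunit ribosomal proteins ran from -0.24 without NC siRNA 2 to a reversed 0.037 without NC siRNA 3. Another reversed median was 0.10 for mitochondrially encoded transcripts with the correction and without NC siRNA 2. HIF1A was also reversed there (log2 fold change 0.18, adjusted p = 0.0278).

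With a replicate block there were 0 genes higher, 1 lower and 1 at least halved (SNRPG). Deviations of same-numbered libraries correlated at 0.23, -0.11 and -0.32, and those of differently numbered libraries at -0.30 to 0.38. These deviations still held the length and GC trends, so they cannot show whether the numbers pair the libraries. Depth limits low genes, since 3 counts are 0.134 to 0.195 CPM.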

Other observations

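Tests in this part were chosen only after the results were seen, except the counts of other splits of the libraries and the SNRPG pseudogene test.

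Without NC siRNA 2 the picture was broader, and 1150 of its 1672 genes were also among the 1690 past the test with the length and GC correction and without that library. Of the list members in the corrected fit without NC siRNA 2, 20 large-subunit and 14 small-subunit ribosomal proteins, 12 G1/S genes and 10 respiratory chain genes were lower past the gene test (1 large-subunit member was higher), and 6 interferon-stimulated genes were higher with 0 lower. After the correction with all 6 libraries, genes past the test included DDX60 (log2 fold change 0.97), IFI44 (0.70), ISG15 (0.93), IL7R (0.81), the interleukin-1 receptor IL1R1 (0.75) and the MHC class I regulator NLRC5 (0.37). Those lower included NT5DC2 (-0.82), the p53 target ZMAT3 (-0.63), the ceramide kinase CERK (-0.53), the sphingosine phosphate receptor S1PR3 (-0.56) and the histone acetyltransferase HAT1 (-0.50). These genes were named after their values were seen, and all 27 calls of that fit were also called without NC siRNA 2. Both fits use the same libraries apart from NC siRNA 2, so this is not an independent check.

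The YBX1 transcript was not lower by the amount that an effective siRNA gives. An exchange of labels is argued against, as what hides a fall of at least 2-fold. A full exchange would put the log2 fold change at 1 or more, but its 95% interval was -0.36 to 0.18. A partial exchange would put levels within a group at least 2-fold apart, but the highest was at most 1.39 times the lowest. An exchange with an siRNA that left the transcript unchanged stays open, because YBX1 marks no library as treated. Reads moving to pseudogenes are argued against, as what hides a fall of at least 2-fold, because the summed level of YBX1 and its pseudogenes still had a log2 ratio of -0.11. Length and GC trends are argued against in the same way, because the log2 fold change after their removal was -0.13. An siRNA that did not lower the transcript at harvest, a transcript that had recovered, or an effect on the protein alone were not tested, since the protein was not analysed here.

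The number of genes called depended on NC siRNA 2, with 1 gene with all 6 libraries and 1672 without it. Its length and GC trends are not the whole of this, since removing them with all 6 libraries gave 27 calls, although the common dispersion fell from 0.0167 to 0.00726. Low depth is argued against by its total count (17.9 in units of 1e+06 counts), above the 15395313 of NC siRNA 3. RNA of leukocytes is argued against by marker levels of 2.19 CPM, inside the range of the other libraries (1.85 to 3.25 CPM), and fibroblast and endothelium markers (34.3 CPM) were also inside theirs (31.9 to 36.8 CPM). The source name of NC siRNA 2 differs in the last digit of the cell line, as does that of NC siRNA 3, and this was not tested. The design names no biological difference between control libraries, and no biological explanation was tested.

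SNRPG had the smallest adjusted p in edgeR among genes with lower values in the libraries labelled YB1 siRNA (0.0698, and 2.62e-11 in DESeq2). A stretch of the siRNA target shared with YBX1 is argued against, since their annotated transcripts share at most 11 bases in a row, below the 15 taken as the least for a target, whereas YBX3 shares 20 with YBX1. Reads lost to SNRPG pseudogenes are argued against by a summed log2 ratio of -1.16, and length and GC trends by a log2 fold change of -1.33 ± 0.17 (SE) after their removal. A response to the YB1 siRNA, including pairing through a short seed, may account for it as a hypothesis, and the siRNA sequence was not used here.

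The 3 against 3 libraries make 10 splits, too few for a share under 0.05. Which side of a mixed split counts as treated is arbitrary, so the larger count of its 2 directions was taken. As many genes higher (1 in the real split, at most 1 in another) came from 2 of the 10 splits, and the count of 0 for lower, doubled and halved genes was met by all 10 (at most 1 in another split for each). As many lists called higher (5, at most 7 in another) came from 6 splits, and as many called lower (13, at most 7 in another) from 1, the real one.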
